A study of Homo sapiens with 7 samples.

How the data were processed

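The binding of Myc to DNA was measured by CUT&RUN in HT29 cells, an established line from a human colon adenocarcinoma. In this assay, cells are held on lectin-coated beads and made permeable with digitonin, and an antibody against the protein of interest guides a nuclease fused to proteins A and G to its sites. The nuclease then cuts the DNA around the antibody, and the released fragments are sequenced. Per the labels, every library came from cells kept for 6 h with oleic acid, a monounsaturated fatty acid, in medium without serum. By their titles, 3 libraries were made with the Myc antibody, 3 were IgG controls and 1 was an input. The labels name the same Myc antibody for the IgG libraries as for the Myc libraries, and the titles were followed here for the groups. No library without oleic acid was analysed here, so the effect of the fatty acid on binding could not be tested.

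The values used were those of 1 peak list for the whole series, in the narrowPeak format of MACS2. Per the submitters' processing notes, the tools were FastQC 0.11.7, BWA 0.7.15, SAMtools 1.5, Picard 2.19.0, MACS2 2.1.2, HOMER 4.11.1 and deepTools 3.5.0, and the genome build was hg38; the notes used here give no settings. For each peak, the authors gave the fold enrichment at the summit, a ratio of the Myc signal to the local control level. The authors also gave the −log10 of the p-value and of the q-value at the summit. Peak names begin with the name of the protein and the list holds 1 value per peak, so it was read here as 1 list over the Myc libraries. Whether IgG or input served as the control, how replicates were joined and whether duplicate fragments were removed are not given in the sources used here. The lowest listed −log10 q was 1.30, which corresponds to a q of 0.0499, so the deposited list ends at about that threshold. Peaks differ in strength as the authors' fold enrichment describes it, and that value was used here within this list, to describe, rank and filter peaks, to compare sets of its peaks or genes, and to recover pileups.

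The depth behind each peak was recovered from the deposited fold and −log10 p. MACS2 computes the fold as the Myc pileup plus 1 over the control level plus 1, and the p-value as a Poisson tail at the same pair of values, so the pair can be solved for a whole-number pileup. For 47016 of the 47017 peaks, a whole-number pileup gave back the listed −log10 p within 0.001. The pileup is the number of fragments that overlap the summit, and the control level is the number expected there from the control and the genome-wide background, which sets a floor. On 2000 simulated peaks the procedure recovered 100% of the pileups. Intervals on a fold are exact Poisson 95% intervals of the pileup with the control level held fixed. Fragments were amplified and carry no molecular identifiers, so these intervals cover counting error only. They say nothing of the spread between the 3 Myc libraries, for which the list holds no values.

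Genes came from an NCBI RefSeq table of assembly GRCh38.p14, which has the same chromosome sequences as hg38, and its positions were used as given, counted from 1. The table gives the start and end of each gene, and neither strand, transcripts nor sequence was used here. The plan, fixed before the data were examined, was to count summits within 1 kb of a transcription start. With no strand to tell the 5′ end, a summit was instead counted as near a gene when it lay within 1 kb of either annotated end, the lower or the higher coordinate, of any of 20037 protein-coding genes on chromosomes 1 to 22, X and Y. This takes in sites at the 3′ end and misses starts inside the gene. For the same reason 25 planned motif patterns, among them the E-box that Myc with its partner MAX recognises, were not searched, since no genome sequence was used here.

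The share of summits near gene ends was set against 1000 random placements, in which all summits of a chromosome were shifted together by a random distance around it. The median log2 fold of peaks near gene ends was compared with that of all other peaks by a permutation test with 100000 resamples. Gene lists were tested with Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over 22 lists, and a list was called at an adjusted p under 0.05. The other genes were not matched to the lists on expression or open chromatin, neither of which was measured here. Odds ratios and their 95% intervals (Woolf's method) were computed after adding 0.5 to each cell of the table. All these tests were two-sided. Within genes that had a peak, the median fold of each list was compared with that of 100000 random sets of as many genes with a peak, a permutation test of list membership adjusted over the 22 lists; this comparison was added after the data were seen. Shares carry Wilson 95% intervals, and peaks per chromosome carry exact Poisson 95% intervals around the number expected from protein-coding genes. Units of these tests are peaks or genes, not libraries, and neighbouring genes can share a peak, so their p-values describe this list and not the variation between cultures.

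Gene lists and the rule for naming genes were fixed before the data were examined. The rule names DGAT1 and DGAT2, all members of the MYC network list, the 10 genes with the highest fold at an end that no other protein-coding gene shares, up to 3 members of each other list with the highest fold, and the 5 strongest peaks over 10 kb from any protein-coding gene end. Of 26 symbols in the MYC network list 25 matched, and the other is an alias of a gene already listed; all symbols of the remaining lists matched. Genes named outside this rule are marked as chosen after their values were seen.

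Alternatives fixed beforehand were a −log10 q of at least 5, peaks above the median fold, 1 peak per interval within 500 bp, leaving out peaks wider than 2 kb with the top 1% by fold, windows of 500 bp, 2 kb and 5 kb, all annotated genes, and a background of genes with any peak within 50 kb. Alternatives chosen after seeing the data were leaving out a segment of chromosome 8 (for peaks per chromosome, with the genes in it), a control level of at most 20, peaks anywhere in a gene, genes outside chromosome 8, merging peaks within 5 kb, and peaks per Mb between the outermost annotated genes. Leaving out wide and top peaks removes many strong peaks, and genes without another peak near an end then count as having none. A call lost in that setting therefore does not stand for fewer bound genes. The random placement, list and permutation routines were tested on simulated data. Summits placed at random gave an observed share of 0.985 times the shifted share, 0 of 10 unchanged lists were called, and 10 of 10 lists with a raised share were called. The peak on the mitochondrial chromosome was left out of all tests of genes, lists and chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The folds of some single genes of the lists are not reported here; these genes stay in the list counts and tests.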

Results

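Binding sites of the transcription factor Myc were mapped in HT29 colon cancer cells after 6 h with oleic acid. The series concerns colon cancer progression in obesity and DGAT1 and DGAT2, the enzymes that catalyse the last step of triacylglycerol synthesis, so the question asked of the peak list was where Myc was found and whether these genes were among its sites. The design held 3 Myc libraries, 3 IgG control libraries and 1 input, and the authors' list gives 1 set of peaks with a fold of Myc over control. The list held 47016 peaks on the nuclear chromosomes, which covered 45.4 Mb. The median peak was 688 bp wide and had a fold enrichment of 4.1, with 90% of the values between 2.42 and 12.5. At the median summit 29 fragments overlapped, against a control level of 5.92. The smallest pileup in the list was 14, and 23.7% of the peaks stood within 0.01 of the lowest control level, 5.09. No value per library was in the list, so no spread between replicates can be given for any peak.

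Myc was found at the ends of 11301 of 20037 protein-coding genes (56.4%, Wilson 95% interval 55.7 to 57.1). The median fold of the strongest peak at these genes was 7.86. The highest fold at an unshared gene end was 50.2 (95% interval 45.0 to 55.8) at ANAPC15, which encodes a subunit of the anaphase-promoting complex. It was followed by PPAT at 41.2 (36.3 to 46.6), the enzyme that commits phosphoribosyl pyrophosphate to purine synthesis. C6orf62 and UBAP2 both had a fold of 39.8. MXD1 had 38.1 and MXD3 37.9, and both encode partners of MAX that act against Myc. OPA3, which encodes a mitochondrial protein, had 37.6, the transcriptional repressor gene CIC 37.3, and the zinc finger genes ZNF460 and ZNF263 34.0 and 33.2. Pileups at these 10 genes ranged from 201 at ZNF263 to 345 at ANAPC15, and control levels from 5.09 at PPAT to 7.20 at CIC.

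Of all summits, 11155 (23.7%) lay within 1 kb of an end of a protein-coding gene. Random placement gave 2.78% on average, with 95% of the draws between 2.48 and 3.09, so the observed share was 8.53 times as high (permutation p = 0.002, two-sided, the smallest that 1000 placements allow). Summits lay near the lower-coordinate end alone in 5104 genes, near the higher-coordinate end alone in 5026 and near both in 1171. Random placement keeps the spacing of peaks but takes no account of open chromatin or of sequence that cannot be mapped.

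Peaks near gene ends were stronger than the others. Their median fold was 7.02 over 11155 peaks, against 3.73 over the other 35861, a difference of 0.91 on the log2 scale (permutation test, p = 1e-05, the smallest that 100000 resamples allow). The share of summits near a gene end was 5.13% (4.53 to 5.79) in the weakest decile of peaks by fold. It was higher in each next decile and came to 63.3% (61.9 to 64.7) in the strongest. Median width was 330 bp in the weakest decile and 1927 bp in the strongest, and median pileup was 20 and 91 fragments.

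**Figure D1:**
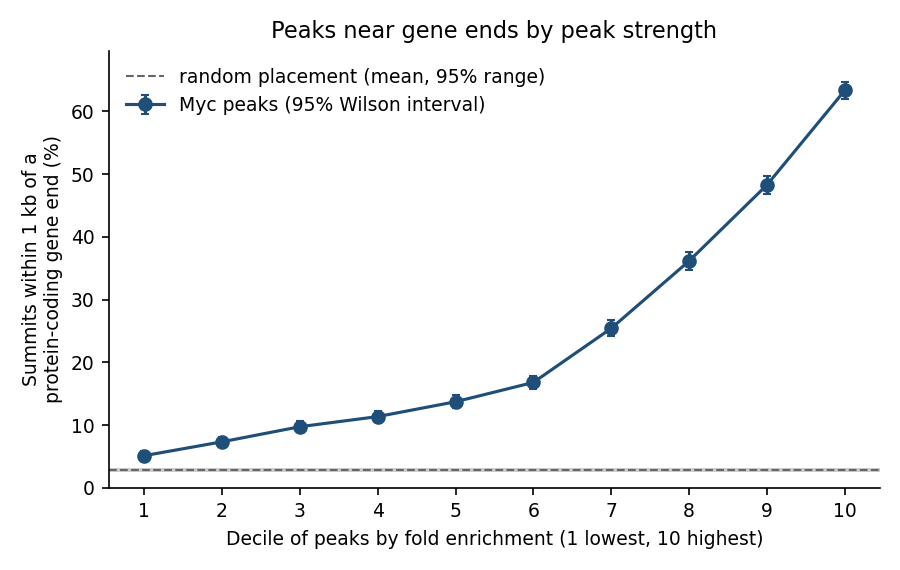
Share of Myc summits within 1 kb of a protein-coding gene end (vertical axis, percent) in deciles of the 47016 peaks ordered by fold enrichment (horizontal axis), with Wilson 95% intervals; the dashed line and band show random placement. The share goes from 5.13% in the weakest decile to 63.3% in the strongest, against 2.78% under random placement.

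Myc peaks were present at both DGAT genes. At DGAT2 (chromosome 11, 75768778 to 75801534, GRCh38) the summit at 75768620 lay 158 bp below the lower end of the gene. Its fold was 7.39 (95% interval 5.74 to 9.37), from a pileup of 66 over a control level of 8.07, and 80.6% of all peaks had a lower fold. At DGAT1 (chromosome 8, 144314584 to 144326852) the strongest summit near an end, at 144327089, lay 237 bp beyond the higher end. Its fold was 4.99 (3.51 to 6.88), from a pileup of 35 over a control level of 6.22, and 62.3% of all peaks had a lower fold. The intervals of these folds overlapped, and the difference between the DGAT1 and DGAT2 sites was not tested. The −log10 q was 34.1 at the DGAT2 site and 13.1 at the DGAT1 site. Among the 11301 genes with a peak, DGAT2 ranked 6154 and DGAT1 8983 by fold, both below the median of 7.86.

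Further peaks lay in and around these genes. Inside DGAT1 a peak at 144324424, 2428 bp from the higher end, had a fold of 5.22 (3.68 to 7.21). A weaker peak near the lower end, at 144315003, had 2.95 (1.79 to 4.63) and also lay near the end of HSF1 (144291604 to 144314720), which encodes a heat shock regulator and whose span overlaps that of DGAT1. Inside DGAT2, peaks at 75782952 and 75786677 had folds of 4.30 (2.86 to 6.22) and 5.57 (3.95 to 7.66). The strongest site within 20 kb of DGAT2, with a fold of 16.7 (13.8 to 20.1), lay 13165 bp beyond its higher end and 511 bp from the lower end of UVRAG, an autophagy gene. No sample without oleic acid entered the list, so these values give presence of Myc after the fatty acid and no change caused by it.

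**Figure D2:**
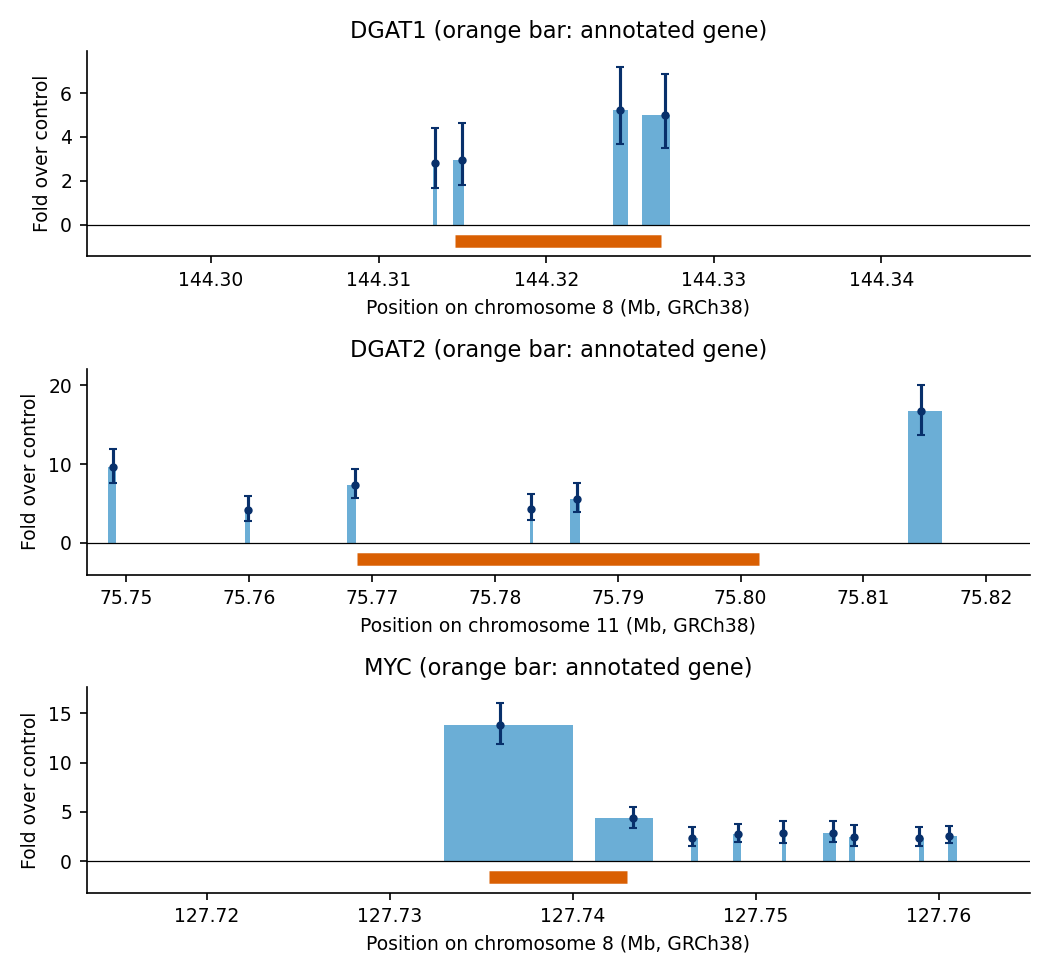
Myc peaks around DGAT1, DGAT2 and MYC, with position in Mb (GRCh38) on the horizontal axis and fold enrichment over control on the vertical axis. Blue bars span each peak, points mark summits with 95% counting intervals, and orange bars mark the genes. The summit near the end of DGAT2 stands at 7.39 and that of DGAT1 at 4.99, while the peak over the lower end of MYC stands at 13.8.

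The gene of Myc itself and most genes of its network carried peaks. Of 25 measured members, 22 (88.0%, 70 to 95.8) had a summit within 1 kb of an end, against 56.4% of all other genes (odds ratio 4.98, 1.61 to 15.4; Fisher's exact test, adjusted exact p = 0.00167). At MYC (chromosome 8, 127735434 to 127742951) a peak 597 bp inside the lower end had a fold of 13.8 (11.9 to 16.1), with a pileup of 174 over a raised control level of 11.6. A separate peak 307 bp beyond the higher end had 4.35 (3.38 to 5.51). At MAX, which encodes the obligate partner of Myc, the summit 247 bp beyond the higher end (chromosome 14, 65102942) had a fold of 10.0 (7.68 to 12.8), and one inside the gene at 65070754 had 18.1 (15 to 21.7).

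The genes of the other MAX partners differed widely in the fold of their peak. MXD1 had a fold of 38.1 (33.4 to 43.3) and MXD3 of 37.9 (33.2 to 43.1), followed by MNT at 15.4 (12.8 to 18.3), MXD4 at 10.3 and MXI1 at 5.58, the last below the median of 7.86 over genes with a peak. In the parallel branch around MLX, whose members sense glucose, MLXIP had 20.8 (17.4 to 24.6), MLX 9.52 and MLXIPL 6.73. MYCL had 14.9 (12 to 18.3). Among regulators of Myc stability and activity, FBXW7 had a fold of 13.5, BIN1 9.52, MYCBP2 8.24, PIM1 6.93, SKP2 6.60, MYCBP 5.43 and ZBTB17 3.21. Of the chromatin cofactors, RUVBL2 had 20.1, BPTF 10.7, WDR5 8.50 and RUVBL1 5.02. The ends of RUVBL2, RUVBL1, SKP2, MYCBP and MYCBP2 with these peaks also lay within 1 kb of an end of another protein-coding gene. No summit within 1 kb of an end was listed for MYCN, MGA and TRRAP, with the nearest at 179684, 4311 and 1192 bp. The median fold of the 22 genes was 9.76, which did not pass the test against other genes with a peak (adjusted permutation p = 0.163). The call on the share was lost without peaks wider than 2 kb and the top 1% by fold (adjusted exact p = 0.632). That setting counts genes whose strong peaks are left out as having none.

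Listed genes of the protein synthesis machinery carried Myc peaks almost without exception. All 74 listed ribosomal protein genes had one (100%, Wilson 95% interval 95.1 to 100, adjusted exact p = 1.03e-17). High folds there were found at, among others, RPLP2 (29.5) and RPL10 (27.7). All 43 listed genes of translation factors and tRNA synthetases had one too (91.8 to 100, adjusted exact p = 2.32e-10). They were led by the threonyl-tRNA synthetase gene TARS1 (25) and the initiation factor genes EIF4B (23.8) and EIF3B (23.5). Of 59 ribosome biogenesis genes, 56 had a peak (94.9%, 86.1 to 98.3; adjusted exact p = 2.32e-10), led by DDX21 (30.5), a nucleolar RNA helicase, DKC1 (30.1), the pseudouridine synthase dyskerin, and WDR12 (28.4), a large subunit assembly factor. In mitochondrial translation and import, 48 of 49 genes had one (98.0%, 89.3 to 99.6; adjusted exact p = 2.32e-10), with MRPS18B at 44.6, TOMM70 at 26.7 and HSPA9 at 22.9. The MRPS18B peak also lay near an end of PPP1R10, the RPLP2 peak near PIDD1, the WDR12 peak near CARF, the EIF3B peak near SNX8 and the TOMM70 peak near LNP1.

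Peaks at these lists were also stronger than at other genes with a peak, in a comparison added after the data were seen. Median folds were 12.8 for ribosome biogenesis, 11.4 for translation factors and synthetases, 11 for ribosomal proteins and 10.7 for mitochondrial translation and import, against 7.86 for all genes with a peak. The differences on the log2 scale were 0.71, 0.54, 0.49 and 0.45, with adjusted p of 2.2e-04, 5.87e-04, 2.2e-04 and 0.00187 in the permutation test, where 2.2e-04 rests on the smallest p that the resamples allow. For ribosome biogenesis the call on the share was lost without peaks wider than 2 kb and the top 1% by fold (adjusted exact p = 0.136). The other 3 lists kept theirs. That setting removes strong peaks and counts their genes as having none, so the loss does not stand for fewer bound genes.

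Genes of growth metabolism and the cell cycle carried peaks more often than other genes. Of 37 nucleotide synthesis genes 31 had one (83.8%, 68.9 to 92.3; adjusted exact p = 0.00125), among them PPAT (41.2), the nucleoside diphosphate kinase gene NME1 (19.2) and APRT (18.5), which salvages adenine. Of 35 genes of glycolysis and glutamine use 30 did (85.7%, 70.6 to 93.7; adjusted exact p = 8.89e-04), among them the lactate transporter gene SLC16A1 (19.9), GLUD1 (19.5) and GAPDH (17.9). In cell cycle and replication, 37 of 40 had a peak (92.5%, 80.1 to 97.4; adjusted exact p = 2.90e-06), with E2F3 at 18.6, the helicase gene MCM7 at 18.3 and CDK4 at 18.0. The peaks of NME1, GLUD1, E2F3 and MCM7 also lay near an end of another protein-coding gene. Median folds were 10.6, 10.0 and 8.38, and of these only that of nucleotide synthesis stood above other genes with a peak (adjusted permutation p = 0.0202, against 0.0804 and 0.559). Without peaks wider than 2 kb and the top 1% by fold, nucleotide synthesis and glycolysis lost their call (adjusted exact p = 0.121 and 0.303), and glycolysis also with a window of 500 bp (0.194). A higher share was not particular to lists linked to Myc. Of 154 symbol families, chosen after the data were seen, 36 were higher and 38 lower. Among the higher were VPS (34 of 35) and GTF (24 of 26), whose genes are in none of the lists.

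Among lipid genes, the lists for synthesis and oxidation carried peaks more often than other genes, and those for storage and uptake did not pass the test. Of 39 fatty acid and cholesterol synthesis genes, 31 had a peak (79.5%, 64.5 to 89.2; adjusted exact p = 0.00486). High folds were found at, among others, ACAT2 (22.5, 18.9 to 26.6) and FASN (17.6, 14.4 to 21.2), the fatty acid synthase. Of 33 genes of fatty acid oxidation and PPAR targets, 27 had one (81.8%, 65.6 to 91.4; adjusted exact p = 0.00414), among them UCP2 at 19.8 (16.7 to 23.3) and ETFB at 14.7. The ACAT2 peak was shared with SOD2 and the ETFB peak with CLDND2. Median folds were 8.86 for synthesis and 6.56 for oxidation, against 7.86 for all genes with a peak, and neither passed the test of strength (adjusted permutation p = 0.380 and 0.250). Both lists lost their call when peaks wider than 2 kb and the top 1% by fold were left out (adjusted exact p = 0.689 and 0.128), and the synthesis list also against genes with any peak within 50 kb (0.0558).

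In triacylglycerol synthesis and lipid droplets, the list that holds DGAT1 and DGAT2, 26 of 39 genes had a peak (66.7%, 51.0 to 79.4), which did not pass the test against 56.4% of other genes (adjusted exact p = 0.270). Its highest folds were at AGPAT1 (13.6, 11.2 to 16.5) and GPAT3 (10.8, 8.40 to 13.8), both acyltransferases of the pathway, and at the lipase gene PNPLA2 (9.39, 7.42 to 11.7). The AGPAT1 peak was shared with RNF5. The median fold of the list, 6.30, did not pass the test against 7.86 for all genes with a peak (adjusted permutation p = 0.162). The share passed the test with a window of 5 kb (adjusted exact p = 0.0304). It also passed without peaks wider than 2 kb and the top 1% by fold (0.0338), where the share of the list fell to 61.5% and that of other genes fell further, to 41.4%, so this call does not stand for more genes with a peak. In fatty acid uptake, binding and activation, 10 of 27 genes had a peak (37.0%, 21.5 to 55.8; adjusted exact p = 0.0597), led by ACSS1 (12.2), SLC27A4 (10.1) and SLC27A2 (9.57, a peak shared with ATP8B4), with a median of 6.89 (adjusted permutation p = 0.559). This lower share passed with a window of 500 bp (adjusted exact p = 0.0415) and, narrowly, among genes outside chromosome 8 (adjusted exact p of 0.05 after rounding). Chosen after their values were seen, the fatty acid transporter gene CD36, the binding protein gene FABP1 and the droplet coat gene PLIN2 had no summit within 1 kb of an end, with the nearest at 6448, 67292 and 3587 bp.

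Genes of intestinal identity did not pass the test as a list, although some of their regulators had strong peaks. Of 44 intestinal epithelium genes, 25 had a peak (56.8%, 42.2 to 70.3; adjusted exact p = 1). High folds were found at transcription factor genes, among them CDX2 at 17.2 (14.9 to 19.7) and HNF4G at 12.7 (10.4 to 15.3), while the median fold of the list, 6.40, did not pass the test against 7.86 for all genes with a peak (adjusted permutation p = 0.210). Of 30 WNT pathway genes 22 had one (73.3%, 55.6 to 85.8; adjusted exact p = 0.0734), led by ZNRF3 (10.4), APC (9.57) and FZD7 (9.03). The WNT share passed when a peak anywhere in the gene was counted (adjusted exact p = 0.00334).

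Stress, lysosome, clock and histone genes carried peaks more often than other genes, by smaller margins for the last 3. Of 34 stress response and hypoxia genes, 31 had a peak (91.2%, 77.0 to 97.0; adjusted exact p = 3.26e-05), with the chaperone gene HSP90B1 at 18.5 and ATF5 and ATF6 at 17.5 and 16.5. Of 38 lysosome and autophagy genes, 30 did (78.9%, 63.7 to 88.9; adjusted exact p = 0.00638), led by UVRAG (16.7), NEU1 (14) and ATP6V1A (13.1). Of 24 circadian clock genes, 19 did (79.2%, 59.5 to 90.8; adjusted exact p = 0.0297), led by TIMELESS (19.2), CRY1 (15.1) and DBP (13.5). Of 47 replication-dependent histone genes, 36 did (76.6%, 62.8 to 86.4; adjusted exact p = 0.00638), led by H4C8 (11.7) and by H2AC11 and H2BC11, which shared a peak with a fold of 9.65. The peaks of ATF5, NEU1, ATP6V1A, TIMELESS and DBP also lay near an end of another protein-coding gene. Median folds were 8.56, 6.80, 9.03 and 6.44, and none of the 4 passed the test of strength (adjusted permutation p from 0.144 to 0.518). All 4 lists lost their call without peaks wider than 2 kb and the top 1% by fold (adjusted exact p = 0.107, 0.104, 1 and 0.457). The clock list also did so with windows of 500 bp, 2 kb and 5 kb (0.185, 0.109 and 0.139), and the histone list with 1 peak per interval (0.334) and with a peak anywhere in the gene (0.302). Against genes with any peak within 50 kb, both the clock and the histone list lost their call (adjusted exact p = 0.146 for each).

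Genes of tissues other than the gut carried peaks less often than other genes. A summit was found at 5 of 37 neuronal genes (13.5%, 5.91 to 28.0), 7 of 41 blood cell genes (17.1%, 8.53 to 31.3), 7 of 37 muscle genes (18.9%, 9.48 to 34.2) and 6 of 37 liver secretory genes (16.2%, 7.65 to 31.1). The adjusted p values of Fisher's exact test were 4.30e-07, 1.07e-06, 1.43e-05 and 2.61e-06, and all 4 lists stayed lower under every alternative run. The strongest of these peaks were at DLG4 (5.74), DBH (4.76) and GRIN1 (3.68) for neurons, CD3E (11), LYZ (7.27) and CD68 (6.57) for blood, TNNC2 (4.88), TNNT2 (3.77) and TNNC1 (3.45) for muscle, and TAT (8.37), TF (7.5) and ASS1 (3.87) for liver. Of these 12 peaks, 5 also lay near an end of another protein-coding gene: DBH near SARDH, GRIN1 near LRRC26, CD68 near EIF4A1, TNNC2 near SNX21 and TF near TOPBP1. Among genes with a peak, median folds of the neuronal, muscle and liver lists, 3.68, 3.43 and 3.74, were below that of other genes (adjusted permutation p = 0.0280, 0.00422 and 0.0144), while that of the blood cell list, 4.88, did not pass the test (0.1305).

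**Figure D3:**
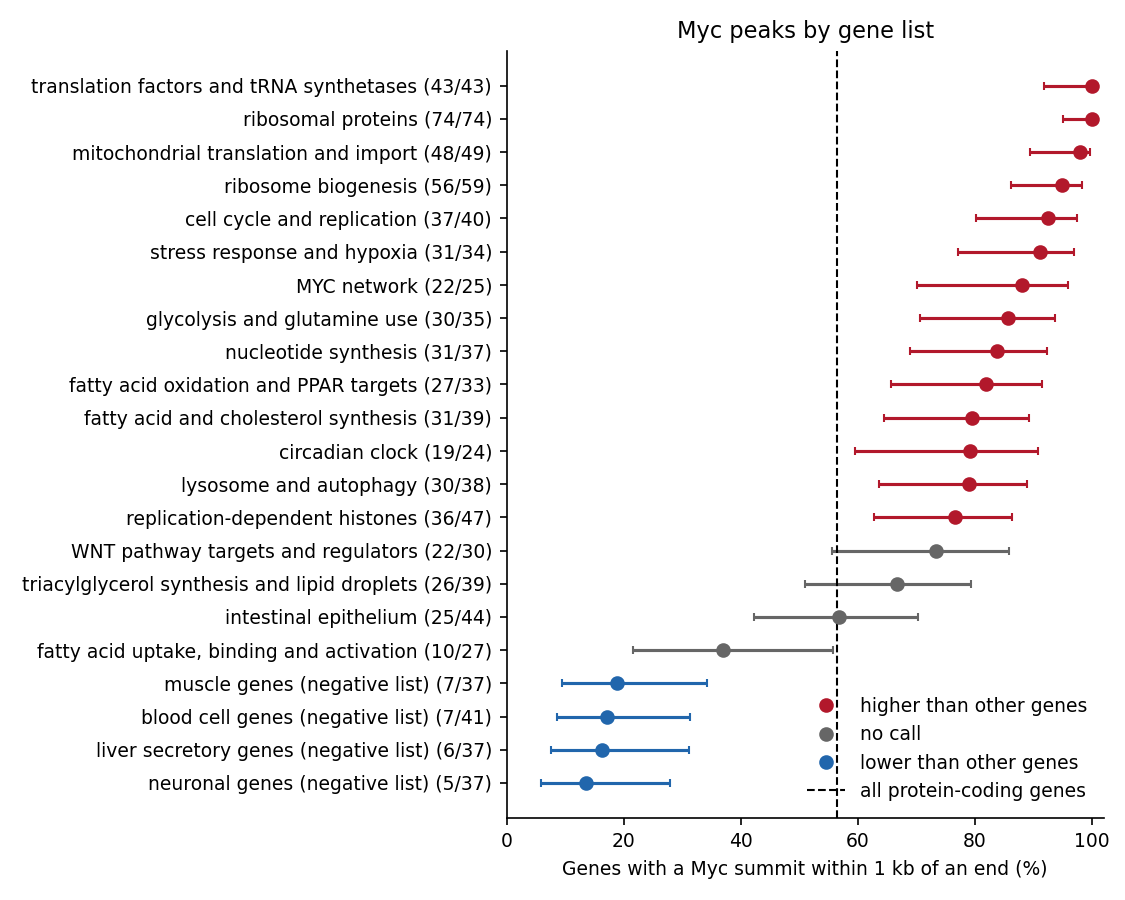
Share of genes in each list with a Myc summit within 1 kb of an end (horizontal axis, percent), with Wilson 95% intervals and counts beside the names. Colours give the call of Fisher's exact test at an adjusted p under 0.05, and the dashed line is the share of all protein-coding genes, 56.4%. Ribosomal proteins and translation genes stand at 100%, and the neuronal, blood, muscle and liver lists stand between 13.5% and 18.9%.

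Some of the strong sites lay away from the ends of protein-coding genes. The 5 strongest peaks over 10 kb from an end of a protein-coding gene had folds between 27.7 and 39.0, with pileups from 168 to 332. The highest was inside SIPA1L3 (chromosome 19, 38172740 to 38174759; fold 39.0), 34.6 kb from its nearest end. The next lay inside GALK2 (chromosome 15, 49169517 to 49172054; 35.7), a sugar kinase gene that also holds a microRNA gene within 2 kb of the summit. Peaks followed inside CASP8 (chromosome 2, 201257427 to 201259500; 30.7), which encodes an initiator caspase, and inside PPP5C (chromosome 19, 46372740 to 46374655; 28.1), which encodes a phosphatase. The fifth was between protein-coding genes (chromosome 14, 50000352 to 50002281; 27.7), within 2 kb of the noncoding gene LINC01588 and 101.6 kb from VCPKMT. Whether these intragenic sites are starts of other transcripts was not examined, since only gene spans were used here.

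Peaks were spread unevenly over the chromosomes. Relative to its number of protein-coding genes, chromosome 8 had 2.12 times the expected peaks (95% Poisson interval 2.05 to 2.2, 3557 peaks), chromosome 13 had 1.97 (1.88 to 2.07), chromosome 20 had 1.48 (1.41 to 1.54), chromosome 15 had 1.42 (1.36 to 1.49) and chromosome 7 had 1.27 (1.23 to 1.32). The lowest ratios among the autosomes were 0.654 on chromosome 14 and 0.685 on chromosome 19, and the X chromosome had 0.444. Per Mb between the outermost annotated genes, chosen after the data were seen, the order differed, with 2.61 on chromosome 19, 2.01 on chromosome 17, 1.90 on chromosome 20, 1.61 on chromosome 8, 0.899 on chromosome 13 and 0.570 on chromosome 14. The chi-square statistic over chromosomes was 5113 on 23 degrees of freedom. The excess on chromosome 8 was reversed among peaks above the median fold, where the ratio was 0.910, and was 1.25 at a −log10 q of at least 5. Fold and q are both taken against the control level. At the same pileup, these settings therefore remove more peaks where the control level is raised. Control levels differed as well, with a median at summits of 9.43 on chromosome 8, 7.20 on chromosome 13, 6.5 on chromosome 20 and 5.09 on chromosome 14.

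Most peaks of chromosome 8 lay in 1 segment that includes MYC. Between positions 114000001 and 142000000, a span of 28 Mb found after the data were seen from its control level, 2754 peaks were called, against 803 on the rest of the chromosome. The median control level was 9.82 in the segment (quartiles 9.17 and 10.8) and 5.56 on the rest of the chromosome. The median fold was 2.59 in the segment and 4.50 on the rest of the chromosome, while median pileups were 27 and 29. Only 2.61% (2.08 to 3.28) of the summits in the segment lay within 1 kb of a protein-coding gene end, against 33.7% (30.6 to 37.1) on the rest of the chromosome. The segment holds 82 protein-coding genes and the rest of the chromosome 633, so it offers fewer gene ends for its many peaks. DGAT1 lies beyond the segment.

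**Figure D4:**
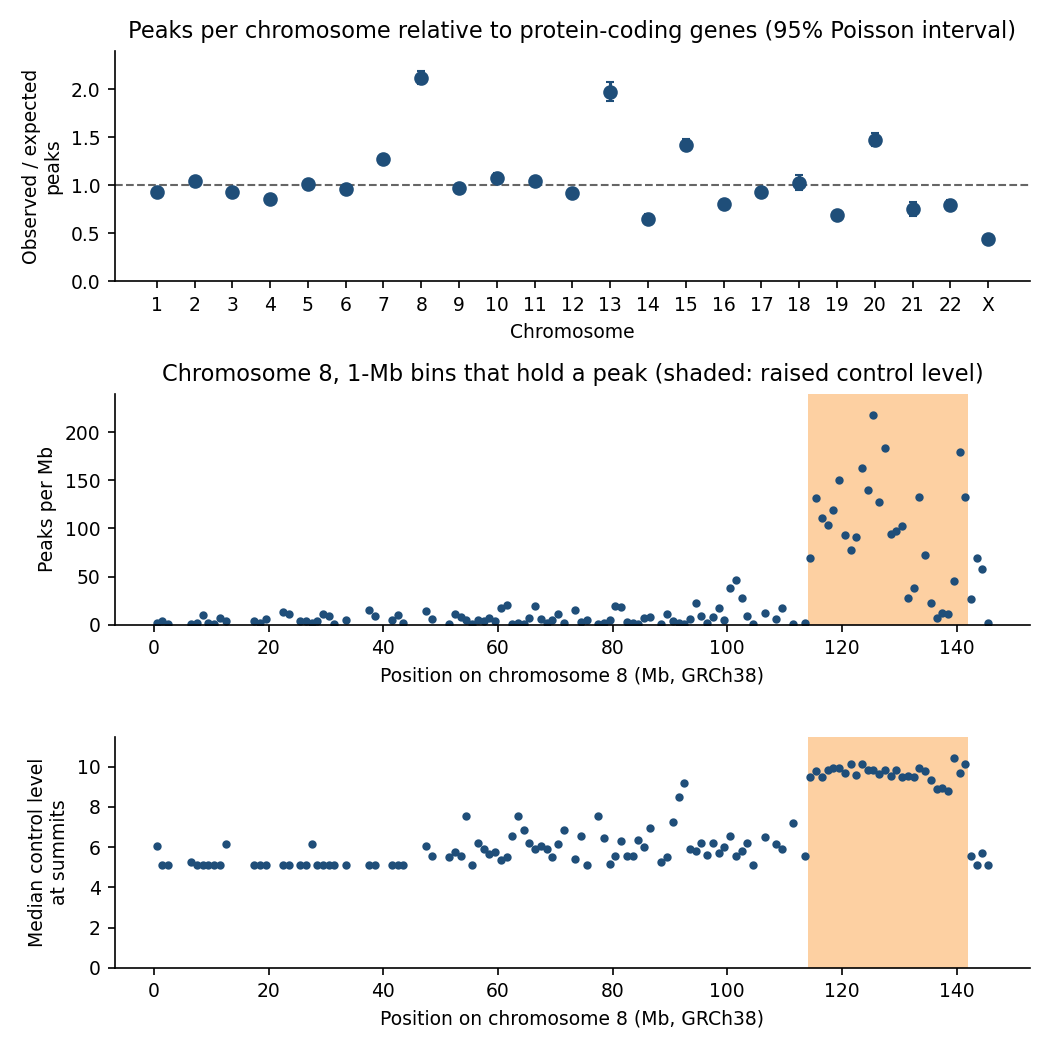
Upper panel, peaks on chromosomes 1 to 22 and X relative to the number expected from protein-coding genes (vertical axis), with 95% Poisson intervals; middle and lower panels, peaks per Mb and median control level at summits along chromosome 8 (position in Mb, GRCh38) in bins of 1 Mb, with the segment of raised control level shaded. Chromosome 8 has a ratio of 2.12, and the median control level is 9.82 inside the segment and 5.56 on the rest of the chromosome.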

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

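The comparison of the mitochondrial copy on chromosome 1 with the mitochondrial chromosome was chosen, and its bounds were set and later adjusted, after the result was seen; the test over other mitochondrial pseudogenes was written down before its result. The list held 1 peak outside the nuclear chromosomes, a signal that no test of genes, lists or chromosomes used. It spanned nearly the whole mitochondrial chromosome (positions 21 to 16551) with a fold enrichment of 7.70 over control.

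Next to it in −log10 p stood 3 peaks at the start of chromosome 1 (629097 to 634582), over MTND1P23, MTND2P28, MTCO1P12 and neighbouring pseudogenes of mitochondrial genes, with folds from 6.21 to 7.45. Reads of mitochondrial DNA spread over most nuclear copies are argued against, since 4 of 467 other mitochondrial pseudogenes (0.857%, 0.334 to 2.18) held a summit. The share was 577 of 16371 for other pseudogenes (3.52%, Fisher's exact test, p = 4.58e-04). These were not matched in kind or position. They include transcribed pseudogenes, of which 27.0% had a summit within 1 kb of an end. A low share over all copies cannot speak against placement on a few close ones. Reads placed on single copies, this one among them, remain open, as the median fold of the 3 peaks was 0.834 times that of the mitochondrial chromosome and their control levels, 768 to 1400, were above the highest of any other nuclear summit, 612. Of the 4 other pseudogenes with a summit, 3 (MTND6P4, MTND5P11 and MTND4P12) lie side by side on chromosome 5 (134924123 to 134928036) with folds of 8.15 to 14.1 and control levels from 15.1 to 47.5, above the median of 5.92 over all summits. Sequence identity, which could separate close copies from distant ones, was not used here, and no biological explanation was tested because the design holds no other condition.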

How the results depend on the processing

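Alternatives on the segment of chromosome 8, the control level, gene bodies, genes outside chromosome 8, merging within 5 kb and the span per Mb were chosen after the data were seen. Of 66 alternative values of the main results, 58 stayed on the same side of their test or within the bounds set for a count. The share of summits near gene ends lay between 3.39 and 13.3 times random placement, and the log2 difference between peaks near gene ends and others between 0.49 and 0.97. Peaks numbered 23494 above the median fold. Leaving out peaks wider than 2 kb and the top 1% by fold left 5 lists called higher instead of 14. Genes whose only peaks were left out counted as having none, which took the genes with a peak from 11301 to 8296. Of the 14 lists, 4 kept their call. Triacylglycerol synthesis and lipid droplets gained one as its share fell less than that of other genes. The difference for histone genes changed sign to -7.38 percentage points and was not called (Fisher's exact test, adjusted p = 0.457). The ratio of chromosome 8, 2.12, was 1.25 at a −log10 q of at least 5, 0.910 above the median fold, 2.23 without wide and top peaks, 0.572 without its segment and the genes in it, 1.71 after merging peaks within 5 kb and 1.61 per Mb between the outermost annotated genes. Of 264 values for single lists, 240 kept their call or lack of one, 18 lost it with the same sign and 5 gained one. The remaining 1, that of the histone genes, lost its call with a change of sign. No paired analysis was possible because the list holds 1 value per peak, so neither a replicate could be left out nor its number used. Motif searches, lists matched on GC content, the 5′ end alone and peaks per Mb of sequence without N were not run, as neither sequence nor strand was used here. Sequencing depth was not varied here.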

Other observations

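The counts of RNA gene classes, which were not tested, and the tests of symbol families were chosen after the data were seen. The test of the control level in the chromosome 8 segment was too. The tests of gene ends, of merged peaks, of list strength and of the control level at ribosome biogenesis genes were written down before their results. Control levels of DDX21, DKC1 and WDR12 had, however, been printed before the last of these. Myc summits also marked genes of small RNAs that are not translated. A summit lay within 1 kb of an end of 223 of 443 tRNA genes (50.3%, Wilson 95% interval 45.7 to 55.0) and of 65 of 154 snRNA genes (42.2%, 34.7 to 50.1). Among those over 10 kb from any protein-coding gene end, 113 of 286 tRNA genes (39.5%, 34.0 to 45.3) and 41 of 117 snRNA genes (35.0%, 27.0 to 44.0) had one. In the same setting the shares were 3.15% (2.12 to 4.64) for snoRNA genes, 11.1% (10.6 to 11.7) for lncRNA genes and 2.42% (2.16 to 2.71) for pseudogenes. These intervals count each gene as independent, although 1 summit can count for several neighbouring genes, so they can be too narrow.

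Over 154 families of protein-coding genes that share the letters of their symbol, 36 carried peaks more often and 38 less often than other genes (Fisher's exact test, adjusted p under 0.05). Olfactory receptor genes had peaks at 2 of 392. None was found at 94 keratin-associated protein genes (KRTAP), 39 beta-defensin genes (DEFB) or 16 protocadherin beta genes (PCDHB). The adjusted p of Fisher's exact test were 6.56e-137, 7.49e-33, 4.26e-13 and 1.63e-05. The test counts each gene as independent, so these p-values can be too small where genes of a family lie side by side. Sequence that cannot be mapped was not accounted for. At the other side stood MRPL with 47 of 49, MRPS with 28 of 28, RPL with 49 of 52 and RPS with 41 of 45. VPS, genes of vesicle sorting, had 34 of 35, and POLR, RNA polymerase subunits, had 30 of 33. The broadest peaks were 27.8 kb over HOXA9 to HOXA11 (chromosome 7, 27165127 to 27192918), 22.9 kb over HOXB9 (chromosome 17, 48615404 to 48638304), 19.1 kb over the noncoding NEAT1 and 15.5 kb over LMNA. At 57 summits the control level was above 100; their median fold was 1.40 and their median distance to a protein-coding gene end 1161 kb.

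Chromosome 8 had an excess of peaks, most of them in the segment from 114000001 to 142000000. More bound gene starts in the segment are argued against as the source of most of its peaks. Of its summits, 2.61% (2.08 to 3.28) lay near a protein-coding gene end. The share was 14.3% for summits elsewhere weighted to the same deciles of −log10 q. With 82 protein-coding genes for 2754 peaks, the segment could hardly reach that share however often its genes were bound. The comparison with summits elsewhere therefore decides nothing, and the argument rests on the 2.61% alone. This share of summits does not tell how often genes there were bound. Genes with a peak numbered 11301 with the peaks of the segment and 11241 without them. Broad sites split into several peaks are argued against as the whole source, because the ratio was still 1.71 (1.63 to 1.78) after peaks within 5 kb were merged. A gain of DNA copies in the segment stays open. The control level at summits there was 1.77 times that on the rest of the chromosome. A raised ratio follows from the choice, since the segment was delimited by its control level. In bins of 1 Mb the median went from 5.54 to 9.5 at the lower edge and from 10.2 to 5.57 at the upper edge. Relative to genes, chromosomes 8, 13, 20, 15 and 7 had the highest peak ratios and the highest median control levels of the autosomes, 6.36 to 9.43. Per Mb, chromosome 19 had the highest ratio, 2.61, at a level of 5.57. These values, read after the data were seen, cannot decide on a gain, as copy number was not measured here. No biological explanation was tested because the design has no second condition.

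The hypothesis that growth genes linked to Myc hold stronger peaks than other genes with a peak was tested on ribosome biogenesis alone. Its median log2 fold was 0.71 higher (permutation test, adjusted p = 2.2e-04), the same comparison as in the Results and not a second test. It does not extend to all growth lists. Glycolysis and glutamine use (0.35 higher, adjusted permutation p = 0.0804) and cell cycle and replication (0.092 higher, 0.559) did not pass, while the other growth lists did. A lower control level at ribosome biogenesis genes is argued against, because their median log2 control level was 0.069 higher (bootstrap 95% interval -0.063 to 0.20) and their median log2 pileup 0.75 higher. The floor of 5.09, close under the median of 5.92 over all summits, left little room for a lower level in any case. Chromatin that is more open at highly used genes may give the same picture; it stays open, since no library of another factor or of accessibility was used here.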
